A study of Mus musculus with 12 samples.

How the data were processed

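The data are 12 gene expression tables from RNA sequencing of primary mouse motoneuron cultures (strain FVB), 3 libraries for each combination of genotype (Smn+/+;SMN2 or Smn-/-;SMN2) and treatment (none or 0.5 µM R-Roscovitine). Per the labels' protocols, total RNA was extracted with a Nucleospin RNA kit and libraries were made with Lexogen's mRNA-Seq Library Prep Kit V2. The submitters' processing notes name FastQC 0.10.1, Trim Galore 0.4.0, Cufflinks 2.2.1 and the GRCm38 build. The names of the deposited tables also carry the word Star; the settings of the alignment, the read length and the strand setting are not given in the sources used here. The authors deposited FPKM per gene, fragment values that Cufflinks normalises for transcript length and sequencing depth, with an interval and a status for each value. The tables hold 39196 entries for 39174 gene identifiers. Of these, 19 identifiers stand on several lines, and their FPKM were summed.

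FPKM tables carry no counts. In genes whose locus is between 200 and 3000 bases long, low FPKM multiplied by the locus length came in whole multiples of 1 smallest common step, which is what 1 read is worth. That step was 0.0349 to 0.0512 FPKM times kilobase, or 19.5 to 28.7 M reads per library. Between 34.6% and 39.1% of the low values up to 10 reads were whole within 0.01 reads, where 2.07% are expected by chance, so the step gives the depth but not the counts of most genes, and no count model was used. Cufflinks' own interval extended a median of 9.04% to 11.1% of the value to each side in genes at 1 FPKM or more, and 25.8% to 33.6% in genes between 1 and 2 FPKM. It covers counting and assignment error only. Between 2 and 8 values per library had a status other than OK. Mitochondrially encoded transcripts took 17.7% to 23.7% of the FPKM sum, and the feature Gm26924 2.62% to 5.05%. The Gm26924 share differed by genotype. Without treatment it was 4.52% to 4.85% in SMA (Smn-/-;SMN2) and 2.83% to 3.81% in control (Smn+/+;SMN2) libraries. With treatment it was 3.57% to 5.05% and 2.62% to 3.39%. Whether this bears on any gene list was not tested. No 2 libraries held the same values. Gene coordinates are those of the tables, 1-based, on GRCm38; of the identifiers, 37604 are in GENCODE M21, and 99.82% of these overlap the same locus there.

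FPKM were scaled between libraries by median-of-ratios factors over the tested genes and transformed to log2(scaled FPKM + 1). Fold changes are on that scale, which understates the change of low genes. Genes with an FPKM of at least 1 in at least 3 of the 12 libraries were tested, 15080 in all, and small RNA genes were left out. Group levels in the text are unscaled FPKM with the SD of 3 libraries. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided) over all 12 libraries and 4 group means, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. There were 7 comparisons: genotype without and with treatment, treatment in each genotype, their interaction, and the genotype and treatment effects averaged. Single values of Smn1 were compared by exact permutation. Without scaling between libraries, the median of all genes moved by no more than -0.0428 on the log2 scale in any comparison. Tables and figures were handled with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

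Gene lists, the rule for named genes, the tests of the 7 comparisons and their alternatives were chosen before the data were examined, except the fits with pairs as a block, as a random effect or as means and the fit without control library 1 in both treatments. The lists cover the SMN complex and snRNPs, p53 targets, apoptosis, calcium channels, sodium and potassium channels, presynaptic genes, neurotransmitter receptors, axon guidance, axonal cytoskeleton and transport, neurotrophin and cytokine signalling, immediate early genes, the kinases that R-Roscovitine inhibits with their partners, the cell cycle, replication-dependent histones, cholesterol synthesis, the integrated stress and unfolded protein responses, heat shock, hypoxia and glycolysis, nuclear and mitochondrial genes of oxidative phosphorylation, ribosomal proteins, the interferon response, neighbours of Smn1 on chromosome 13, Hox groups 4 to 8 and 9 to 13, and markers of motoneurons, interneurons, sensory neurons, neural progenitors, astroglia, oligodendrocytes, Schwann cells and neural crest, fibroblasts, endothelium and macrophages. Lists with at least 5 tested members, 35 in all, were tested with limma's camera at a preset correlation of 0.01, and again with a correlation estimated from the libraries and with fry, whose directional test asks whether a list moves on balance one way and whose mixed test asks for change in either direction. Markers of smooth muscle, erythroid and skeletal muscle cells had too few tested members and are given as levels. Where a symbol stood for several identifiers, the one with the highest mean FPKM was taken. The named genes were Smn1, Cacna1a, Cacna1b, Cdk1, Cdk2, Cdk5, Cdk7, Cdk9 and Cdkn1a; per comparison the 12 called genes with the largest rise and fall and no overlap between groups, or, where fewer than 5 were called, the 5 with the lowest p in that direction; and in each called list the 4 members with the lowest p in its direction. Gene models without a proper name were counted but not all named, and a few named genes are not reported here.

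The labels give the groups the same replicate numbers. Within a genotype, treated and untreated libraries of the same number deviated from their group means together: the correlations across genes were 0.222, 0.578 and 0.317 in control and 0.559, 0.506 and 0.428 in SMA libraries, and each of the 6 libraries of a genotype correlated best with its own number. Treatment and interaction tests were therefore also run with these pairs as a block, and the averaged genotype effect with the pairs as a random effect and with 1 mean per pair; those values stand beside the results they change. The pairing comes from the values and the shared numbers, not from a label.

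The test was checked on simulated libraries with the means and spreads of the 15080 genes and 200 changed genes. For the untreated genotype comparison it recovered 33.1% of genes changed 1.5-fold, 73.7% of those changed 2-fold and 97.3% of those changed 4-fold, with 6.4 false calls on average. For treatment in SMA it recovered 21.5%, 69.9% and 98.2%, and for the interaction 5.07%, 36.4% and 85.8%. For the averaged genotype effect it recovered 60.0%, 89.3% and 99.7% with 8.6 false calls, and 35.8 false calls with a correlation of 0.38 within pairs. With that correlation and no changed gene it made 0.6 false calls on average. In simulated libraries of independent genes, camera called 20 of 20 raised lists and 0 of 600 unchanged ones. Members of real lists can move together, so this does not give camera's rate of false calls there. Other splits of the 6 untreated libraries called a median of 9 real lists. The alternatives were a pseudocount of 0.1, a filter of 5 FPKM or none, unscaled, quantile-normalised and TPM-rescaled values, small RNA genes kept, eBayes with robust or without trend, library weights, genes with failed estimates left out, fits to the compared groups alone, the replicate number as a block, and leaving out each library.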

Results

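Gene expression was measured by mRNA sequencing in 12 libraries of primary mouse motoneuron cultures of the FVB strain. The mice carried the human SMN2 transgene and were either wild type at the mouse Smn1 locus (Smn+/+;SMN2, called control here) or null for it (Smn-/-;SMN2, called SMA here, for spinal muscular atrophy). Smn1 encodes the survival motor neuron protein, which assembles the small nuclear ribonucleoproteins of the spliceosome and is lacking in spinal muscular atrophy. Cultures were left untreated or received 0.5 µM R-Roscovitine, an inhibitor of cyclin-dependent kinases that also prolongs the opening of presynaptic Cav2 calcium channels. This gave 4 groups of 3 libraries each. The deposited values are FPKM per gene, without counts, and their low values put the depth at 19.5 to 28.7 M reads per library. The mean depth was 26.5 ± 1.98 M reads (SD, n = 6) in control libraries and 22.2 ± 2.05 M reads (SD, n = 6) in SMA libraries. Between 14463 and 14581 genes per library reached an FPKM of 1. Nothing in the labels says that libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, part of which may be technical.

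Smn1, the targeted gene (ENSMUSG00000021645, GRCm38 chromosome 13, 100124852 to 100137690), separated the genotypes in every library. In untreated control libraries it read 30.9, 41.2 and 51.2 FPKM, and in untreated SMA libraries 6.11, 7.19 and 8.58 FPKM. With R-Roscovitine the control libraries held 45.1, 38.2 and 39.2 FPKM and the SMA libraries 6.82, 5.04 and 7.35 FPKM. The SMA mean was 17.7% of the control mean without and 15.7% with the compound. The settings of the alignment are not given, so reads of the human SMN2 transgene that aligned to Smn1 are not excluded in either genotype, and these values may not measure mouse Smn1 alone. An exact two-sided permutation test of each genotype difference gave p = 0.1, the smallest that 3 libraries against 3 allow. R-Roscovitine left Smn1 within the spread of the libraries: the mean went from 41.1 ± 10.2 to 40.8 ± 3.77 FPKM in controls (SD, n = 3; exact permutation p = 1) and from 7.29 ± 1.24 to 6.40 ± 1.21 FPKM in SMA (SD, n = 3; exact permutation p = 0.5).

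The comparison of SMA with control cultures without treatment asks what the loss of Smn1 does to these cells. By limma, Smn1 fell by 2.28 ± 0.19 (SE) on the log2 scale (adjusted p = 0.000308) and was the 1 gene of 15080 tested to pass the threshold. By camera with its preset correlation of 0.01, neural progenitor and astroglia markers were higher in SMA, and presynaptic, interneuron and immediate early genes lower. No list passed with a correlation estimated from the libraries (lowest adjusted p = 0.509 with an estimated correlation) or with fry's directional test (lowest adjusted p = 0.156). Fry's mixed test, which asks for change in either direction, called 2 lists, the SMN complex and snRNPs, which hold Smn1, and progenitor markers (adjusted p = 0.0475). Olig2, a transcription factor of the ventral progenitor domain that forms motoneurons and oligodendrocytes, had 8.56 ± 4.27 FPKM in SMA and 1.67 ± 0.581 FPKM in control cultures (SD, n = 3). Slc1a3, the glial glutamate transporter GLAST, had 80.2 ± 14.6 against 42.0 ± 12.0 FPKM. Syn1, which encodes the synaptic vesicle protein synapsin I, had 41.2 ± 1.16 against 77.2 ± 18.4 FPKM (SD, n = 3).

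Of the 18 progenitor markers tested, 16 were higher in SMA, with a median log2 difference of 0.77, and 13 rose when adjusted over the list alone. They included Sox1, at 24.3 ± 4.10 against 13.2 ± 2.24 FPKM, and Nkx2-2, at 3.91 ± 0.535 against 1.84 ± 0.355 FPKM (SD, n = 3). Of 14 astroglia markers, 12 were higher (median 0.82), and 7 rose and 1 fell when adjusted over the list alone. Mlc1, a membrane protein of astrocyte endfeet, had 8.95 ± 2.40 against 3.23 ± 0.852 FPKM, and Ttyh1 117 ± 51.8 against 40.1 ± 22.1 FPKM. All 26 replication-dependent histone genes were higher (median 0.49), and 12 rose when adjusted over the list alone. These genes sit near the floor, with a list median of 1.70 FPKM over all libraries. Hist1h1e, a linker histone, had 8.37 ± 1.61 against 4.41 ± 0.806 FPKM. Fibroblast markers, in contrast, had a median log2 difference of -0.15 over 14 members, and endothelial markers -0.08 over 5.

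Of 34 presynaptic genes, 30 were lower in SMA (median log2 difference -0.39) and 10 fell when adjusted over the list alone. Rab3a, a GTPase of synaptic vesicles, had 61.5 ± 0.923 against 111 ± 36.1 FPKM (SD, n = 3). Of 18 interneuron markers, 16 were lower (median -0.51) and 5 fell when adjusted over the list alone. Gad1, which makes GABA, had 57.4 ± 4.29 against 108 ± 36.0 FPKM, and Slc6a5, the neuronal glycine transporter GlyT2, 14.6 ± 2.45 against 25.8 ± 3.68 FPKM. Some interneuron markers were highest in control library 1. Lhx1 had 24.3, 10.4 and 12.1 FPKM in control and 13.2, 8.88 and 16.7 FPKM in SMA libraries. Gad1 had 147, 100 and 76.7 FPKM in control libraries, but Gad1 and Slc6a5 did not overlap between untreated genotypes. Of 12 motoneuron markers tested, 10 were lower (median -0.38) and 2 fell when adjusted over the list alone, Chodl among them at 4.57 ± 1.45 against 11.8 ± 5.66 FPKM. Of 21 motoneuron markers in the files, 9 stayed below 1 FPKM in every library and were not tested. Chat, Mnx1, Isl1, Isl2, Lhx3 and Slc5a7 were among these, so the tested list lacks several genes that define motoneurons. Immediate early genes had a median of -0.58 over 31 members, with Atf3 at 1.38 ± 0.800 against 4.03 ± 1.55 FPKM. Voltage-gated calcium channel subunits had a median of -0.28, and 19 of 20 were lower. Cacna1b, the Cav2.2 pore, had 9.21 ± 1.84 against 14.2 ± 3.68 FPKM, and Cacna1a, the Cav2.1 pore, 14.5 ± 0.908 against 17.6 ± 2.64 FPKM. No calcium channel or immediate early gene passed, even when adjusted over the list alone.

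Further lists passed the list threshold by camera, though none with a correlation estimated from the libraries (adjusted p from 0.514 to 0.674 with an estimated correlation). Genes of the integrated stress and unfolded protein responses had a median of -0.29 over 26 members, with Herpud1 at 21.3 ± 4.31 against 40.6 ± 4.58 FPKM. The medians were -0.24 for 29 neurotransmitter receptors, -0.22 for 27 sodium and potassium channels and -0.20 for 32 axonal cytoskeleton and transport genes. They were -0.14 for 37 axon guidance genes and -0.36 for 10 Hox genes of groups 9 to 13. Several of these Hox genes were lowest in SMA library 1 and highest in control library 1. Hoxa10 had 7.86, 13.1 and 12.3 FPKM in SMA against 17.8, 11.7 and 14.4 FPKM in control libraries. With the compound it had 7.61, 15.4 and 11.8 against 13.8, 14.1 and 11.7 FPKM. Others, such as Hoxb9 (113 to 148 against 153 to 206 FPKM), did not overlap between untreated genotypes. Whether the fall rests on genotype or on libraries 1 was not tested. Ina, a neurofilament subunit, had 53.9 ± 1.28 against 91.2 ± 25.5 FPKM, and Grin1, the obligate NMDA receptor subunit, 8.91 ± 1.19 against 18.3 ± 6.35 FPKM. Cell cycle genes had a median of 0.12 over 37 members, with Ccnb1 at 83.6 ± 6.26 against 58.0 ± 16 FPKM, and ribosomal protein genes 0.09 over 56. The 13 protein-coding transcripts of mitochondrial DNA had a median of 0.26 and were not called with quantile normalization. Among these 9 lists, 1 sodium or potassium channel gene rose when adjusted over the list alone.

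Camera with the preset correlation called these 17 of 35 lists, 6 up and 11 down, with adjusted p from 1.02e-10 for histones to 0.0425 for motoneuron markers. At an unadjusted p under 0.05 limma gave 2115 genes, where 754 are expected by chance. Leaving out untreated control library 2 gave 2 called genes, leaving out treated SMA library 2 gave 6, and weighting the libraries by their spread gave 359. A block on the replicate number gave 318.

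At the settings given above, without weights or a block on the replicate number, no gene but Smn1 passed. The named genes with the lowest unadjusted p were higher for Nkain4, Lpar1, Kcnj10, Kif6 and Slc15a2, and lower for PVT1_1, Sgip1, Abcg4 and Nfil3, with adjusted p from 0.0633 for PVT1_1 to 0.217 for the others. Kcnj10, the glial inward rectifier Kir4.1, had 13.7 ± 5.12 FPKM in SMA and 1.58 ± 0.795 FPKM in control cultures. Lpar1, a lysophosphatidic acid receptor, had 24.9 ± 3.87 against 12.4 ± 1.46 FPKM, and Sgip1, an endocytic adaptor, 19.6 ± 1.15 against 38.4 ± 6.99 FPKM. PVT1_1, a noncoding feature, had 1.85 ± 0.403 against 9.08 ± 4.36 FPKM (SD, n = 3). The other 18 lists were not called in untreated cultures (adjusted p from 0.146 to 0.971). Their medians were 0.04 for the SMN complex and snRNPs, whose mean was -0.06 and of which Smn1 fell, 0.05 for p53 targets, 0.06 for apoptosis, -0.02 for neurotrophin and cytokine signalling, -0.05 for the kinases that R-Roscovitine inhibits, -0.07 for cholesterol synthesis, -0.10 for heat shock, -0.14 for hypoxia and glycolysis, 0.01 for nuclear oxidative phosphorylation genes and -0.11 for the interferon response. They were 0.06 for the neighbours of Smn1, 0.12 for Hox groups 4 to 8, -0.43 for sensory neuron, 0.39 for oligodendrocyte, 0.07 for Schwann cell and neural crest and 0.03 for macrophage markers, which the test put in the lower direction. Single kinases were close in both genotypes: Cdk5 had 14.6 ± 0.846 against 16.2 ± 3.54 FPKM, Cdk2 20.1 ± 3.44 against 21.2 ± 3.20 FPKM and Cdk1 130 ± 8.49 against 119 ± 15.9 FPKM. Cdk7, Cdk9 and Cdkn1a did not pass either (adjusted p = 0.548, 0.842 and 0.467 by limma).

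**Figure D1:**
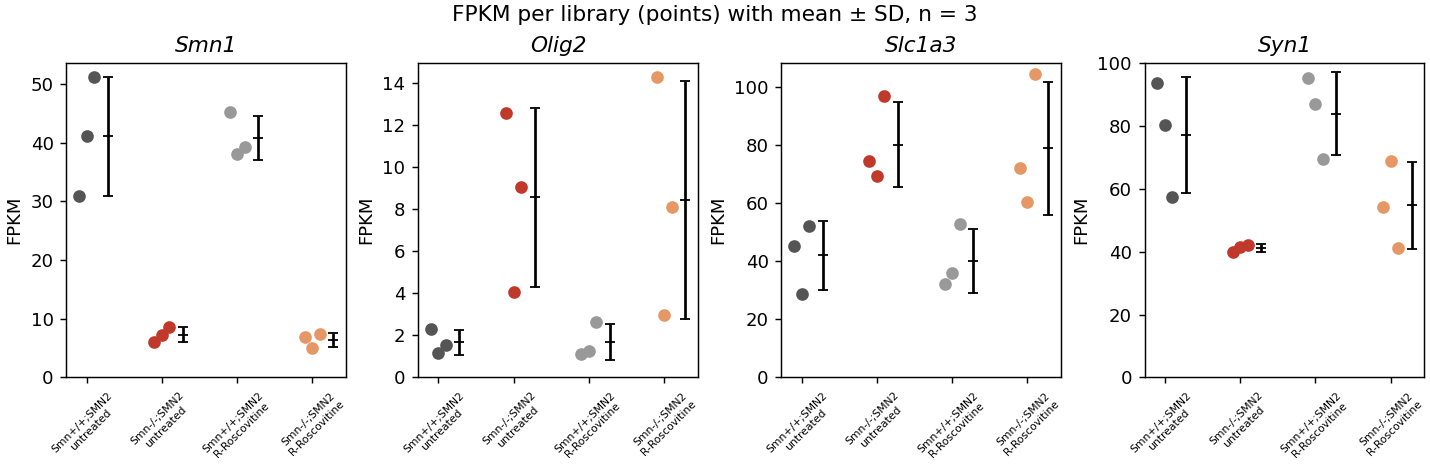
FPKM of Smn1, Olig2, Slc1a3 and Syn1 in each library by group, with the group mean and SD beside the points (n = 3). The 6 SMA libraries lie below the 6 control libraries for Smn1; by limma no other of the 4 genes passed in either genotype comparison within a treatment.

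The same comparison in cultures that had received R-Roscovitine asks whether the genotypes still differed with the compound. Smn1 fell by 2.49 ± 0.19 (SE) on the log2 scale (limma, adjusted p = 0.000107) and was again the 1 gene called. By camera, progenitor, astroglia and histone genes were higher and presynaptic and interneuron genes lower in SMA. No list passed with an estimated correlation (lowest adjusted p = 0.40 with an estimated correlation) or with fry's directional test (lowest adjusted p = 0.0872). Its mixed test called 3, the SMN complex and snRNPs, histones (adjusted p = 0.024) and progenitor markers (adjusted p = 0.0307). Notch1, a receptor that maintains progenitors, had 38.4 ± 9.06 FPKM in SMA and 19.6 ± 8.44 FPKM in control cultures (SD, n = 3). Sox9, a glial fate factor, had 23.6 ± 6.23 against 13.5 ± 3.74 FPKM.

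The 18 progenitor markers had a median log2 difference of 0.73 and 13 rose when adjusted over the list alone. The 14 astroglia markers had a median of 0.78, and 8 rose and 1 fell when adjusted over the list alone. Several of these markers were far lower in SMA library 2 than in SMA libraries 1 and 3. With the compound Gfap had 0.469 against 2.77 and 1.90 FPKM, Aldoc 7.14 against 35.1 and 28.8 FPKM and Olig2 2.98 against 14.3 and 8.09 FPKM, and untreated Gfap had 0.410 against 3.25 and 2.68 FPKM and Aldoc 6.64 against 28.8 and 27.6 FPKM. In treated control libraries Aldoc had 5.70, 8.61 and 7.26 FPKM, so its rise came from SMA libraries 1 and 3. Without treated SMA library 2 the astroglia median was 0.96, without library 1 0.79 and without library 3 0.61. The 26 histone genes, all higher, had a median of 0.67 and 17 rose when adjusted over the list alone. Hist1h1a had 2.41 ± 0.891 against 0.676 ± 0.345 FPKM. Ribosomal protein genes had a median of 0.16 over 56 members and 1, Rps14, rose when adjusted over the list alone, at 383 ± 21.6 against 245 ± 32.4 FPKM. The presynaptic median was -0.26, with Sv2c at 13.3 ± 3.67 against 22.7 ± 5.24 FPKM, and the interneuron median -0.37, with Slc17a6, the vesicular glutamate transporter VGLUT2, at 21.3 ± 3.15 against 34.0 ± 13.2 FPKM. Neurotransmitter receptors had a median of -0.27 and 1 fell when adjusted over the list alone, Htr2a, at 1.83 ± 0.636 against 3.76 ± 0.357 FPKM. Immediate early genes had a median of -0.46, with Npas4 at 2.08 ± 0.422 against 10.7 ± 7.42 FPKM, and stress response genes -0.21. The mitochondrially encoded median was 0.16 and turned to -0.03 with quantile normalization. Calcium channels (median -0.10, adjusted p = 0.159) and motoneuron markers (median -0.08, adjusted p = 0.493) were not called here.

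Camera called these 10 of 35 lists, 5 up and 5 down, with adjusted p from 4.87e-15 for histones to 0.0279 for stress response genes. Limma gave 1941 genes at an unadjusted p under 0.05. With library weights 12 genes were called, and with the replicate number as a block 230. Leaving out treated SMA library 2 raised the gene count to 211, leaving out untreated control library 1 gave 5, and leaving out treated control library 1 lowered the list count to 6.

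Genes near the threshold included Nkain4, with 8.24 ± 3.17 against 2.2 ± 0.391 FPKM (SD, n = 3), and, lower in SMA, Nars2, Fibin, Cnot2 and Snx25 (limma, adjusted p = 0.163 for each). Nars2, the mitochondrial asparaginyl-tRNA synthetase, had 3.10 ± 0.302 against 6.35 ± 0.687 FPKM, and Cnot2, a subunit of the CCR4-NOT deadenylase, 16.2 ± 2.61 against 25.2 ± 1.37 FPKM. Across all 15080 genes, the genotype differences with and without R-Roscovitine had a correlation of 0.648 and a slope of 0.626. Genes are not independent replicates, and treated and untreated libraries of the same number resembled each other. Simulated libraries with such pairs and no genotype difference gave a correlation of 0.377, and the other 9 ways of splitting the 6 pairs into genotypes gave 0.106 to 0.606.

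Averaging the genotype difference over both treatments uses 6 libraries per genotype and asks what the genotypes differ in regardless of the compound. The SEs given here count all 12 libraries as independent, though treated and untreated libraries of the same number resembled each other. These SEs may therefore be too small. With 1 mean per pair limma called Smn1 alone. Smn1 fell by 2.39 ± 0.13 (SE) on the log2 scale. Among the genes that were higher in SMA, Kcnj10 differed by 2.52 ± 0.33 (SE), with 13.7 ± 5.12 and 11.3 ± 6.78 FPKM in untreated and treated SMA libraries against 1.58 ± 0.795 and 1.02 ± 0.927 FPKM in controls. Olig1 differed by 2.34 ± 0.41, Olig2 by 1.73 ± 0.32 and Fgfbp3, a secreted FGF-binding protein, by 2.43 ± 0.39. Ednrb, the endothelin B receptor, reached 111 ± 29.0 FPKM in untreated SMA and 30.9 ± 14.3 FPKM in untreated control libraries (SD, n = 3).

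Limma, counting all 12 libraries as independent, called 675 genes, 425 up and 250 down. With values rescaled to a common sum per library the split turned, with 325 up and 493 down. With library weights limma called 1980, with the replicate number as a block 1746, and with no filter beyond values above 0 it called 1. Over all genes tested, the genotypes did not overlap in either treatment in 448 higher (2.97%) and 341 lower genes (2.26%), of which 281 and 162 were called. In untreated libraries alone they did not overlap in 9.78% of genes as higher and 10.1% as lower, and in treated ones in 9.56% and 7.97%, where chance gives 10% over both directions. Genes are not independent, so these shares are no test. The other leading genes that were higher were Igsf11, Car3, Ttyh1, Vtn and Nkain4, with log2 differences of 1.77, 1.70, 1.63, 1.56 and 1.51. Those that were lower were Msx2, Rgs4, Fibin, Chodl, Ralyl, Gpr50, Ptx3, Rasgrf1 and Cdh3, with log2 differences from -1.40 for Msx2 to -0.96 for Cdh3. Rgs4, a neuronal regulator of G protein signalling, had 9.78 ± 2.05 FPKM in untreated SMA and 25.9 ± 16.5 FPKM in untreated control libraries.

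The counts and SEs by list come from the fit that counts all 12 libraries as independent. With 1 mean per pair no gene but Smn1 passed over all genes, and the counts adjusted over the list alone were not redone with pairs. By list, 10 of 18 progenitor markers rose over all genes and 14 when adjusted over the list alone, with Sox1 differing by 0.86 ± 0.14 (SE) and Notch1 by 0.92 ± 0.20. Of 14 astroglia markers 7 rose, and 9 rose and 1 fell when adjusted over the list alone, with Mlc1 at 1.25 ± 0.22, Slc1a3 at 0.98 ± 0.17 and Fgfr3 at 0.94 ± 0.21. Of 26 histone genes 9 rose, and 23 when adjusted over the list alone. Of 34 presynaptic genes 6 fell, and 15 fell and 1 rose when adjusted over the list alone, with Syn1 at -0.71 ± 0.14 and Cplx1 at -0.65 ± 0.15. Of 18 interneuron markers 1 fell, Slc6a5 (-0.71 ± 0.14), and 9 when adjusted over the list alone. Receptors had 3 fallen members, Htr2a, Grin1 and Gabra2, and 7 when adjusted over the list alone. Axon guidance genes had 1 risen and 2 fallen members, Crmp1 and Efna5 the lower ones, and 8 fell and 1 rose when adjusted over the list alone. Immediate early genes had 2 fallen members, Atf3 and Dusp4, and 1 risen, against 9 and 1 when adjusted over the list alone. Of the stress response genes Herpud1 fell, of the axonal cytoskeleton genes Ina, and Cenpf of the cell cycle genes and Rps14 of the ribosomal protein genes rose.

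Camera called 16 of 35 lists, 6 up and 10 down, with adjusted p from 2.53e-15 to 0.0452. None passed with an estimated correlation (lowest adjusted p = 0.336 with an estimated correlation). Fry's directional test called 3, histones and progenitor markers (adjusted p = 0.0193 for each) and astroglia markers (adjusted p = 0.0249), and its mixed test 20, but both counted both libraries of a same-numbered pair as independent. With 1 mean per pair the directional test called 0 lists (lowest adjusted p = 0.224) and the mixed test 2, the SMN complex and snRNPs and ribosomal proteins (adjusted p = 0.00502). Camera then called 16, none of them with an estimated correlation (lowest adjusted p = 0.626 with an estimated correlation). The count of 675 depends on treating both libraries of a same-numbered pair as separate: with the pairs as a random effect limma called 3 genes, Kcnj10, Nkain4 and Smn1, and with 1 mean per pair it called Smn1 alone (adjusted p = 0.000536), with adjusted p from 0.170 to 0.206 for the other genes named here that had passed. Leaving out single libraries gave 87 (untreated control 2), 123 (untreated SMA 1), 6 (untreated SMA 3), 6 (treated control 1), 386 (treated control 2), 6 (treated SMA 1), 1350 (treated SMA 2) and 36 genes (treated SMA 3), and leaving out control 1 in both treatments, chosen after its values were seen, gave 38.

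**Figure D2:**
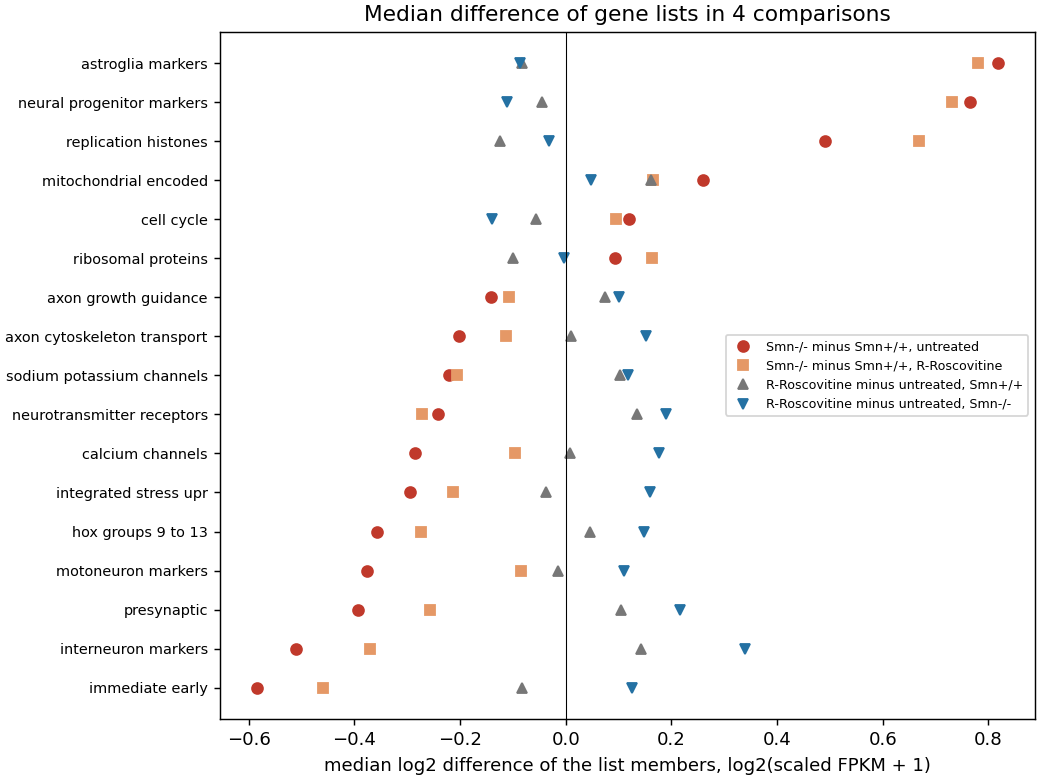
Median log2 difference (x axis, log2 of scaled FPKM + 1) of the 17 lists called by camera in untreated cultures (y axis), in 4 comparisons; none passed there with an estimated correlation. Progenitor and astroglia markers lie near 0.8 in both genotype comparisons, and presynaptic genes at -0.39 and -0.26.

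The effect of R-Roscovitine in control cultures asks what the compound does to cells with intact Smn1. No gene passed. Neurotransmitter receptors had a median log2 difference of 0.13 over 29 members (24 higher), with Gabra5 at 32.3 ± 8.03 FPKM with and 25.3 ± 3.38 FPKM without the compound (SD, n = 3). Presynaptic genes had a median of 0.10 (30 of 34 higher), with Vamp2, the vesicle SNARE synaptobrevin 2, at 326 ± 26.8 against 248 ± 38.2 FPKM. Ribosomal protein genes had a median of -0.10 (46 of 56 lower), histone genes -0.12 and cell cycle genes -0.06, with Cenpf, a kinetochore protein, at 32.7 ± 2.30 against 42.6 ± 8.14 FPKM. The mitochondrially encoded transcripts had a median of 0.16, with mt-Nd3 at 4166 ± 62.8 against 3342 ± 505 FPKM. No member of these 6 lists passed, also when adjusted over the list alone.

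Camera called these 6 lists, 3 up and 3 down, with adjusted p from 1.88e-05 to 0.0168; none passed with an estimated correlation (lowest adjusted p = 0.923 with an estimated correlation) or with fry's directional test (lowest adjusted p = 0.986), and its mixed test called 0. Limma gave 200 genes at an unadjusted p under 0.05, below the 754 expected by chance, and with the same-numbered pairs as a block 0 called genes and 554 at an unadjusted p under 0.05. The block added sodium and potassium channels (adjusted p = 0.0442) and interneuron markers (adjusted p = 0.0426) to the called lists, and none of the 8 passed with an estimated correlation (lowest adjusted p = 0.495 with an estimated correlation). With the block fry's mixed test called 1 list, mitochondrially encoded transcripts (adjusted p = 0.0226). Leaving out treated control library 1 left 1 list, and leaving out untreated control 1, treated control 2 or treated control 3 gave 11, 10 and 11. Without treated control 1 the presynaptic median was -0.03 and the cell cycle median 0.03, and without untreated control 3 they were -0.00993 and 0.01. Leaving out control 1 in both treatments, chosen after the results were seen, gave 2 lists and a ribosomal protein median of 0.0441.

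The lowest unadjusted p among named genes went to Ndufaf4, a complex I assembly factor, at 27.5 ± 0.837 against 20.6 ± 2.36 FPKM, and Tmsb15b2, at 11.6 ± 3.55 against 6.85 ± 1.07 FPKM (SD, n = 3; limma, adjusted p = 1 for each). Ccdc62, Zfp691 and Lenep were lower, at 0.675 ± 0.270, 1.54 ± 0.482 and 0.0551 ± 0.0692 FPKM with and 1.64 ± 0.270, 3.18 ± 0.700 and 1.58 ± 0.554 FPKM without the compound. Cdkn1a, the p21 gene that is induced when p53 is active, had 159 ± 27.8 against 171 ± 18.7 FPKM, and Cdk5 15.0 ± 0.513 against 16.2 ± 3.54 FPKM.

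In SMA cultures the effect of R-Roscovitine asks whether the compound shifts expression in cells that lack Smn1. No gene passed here either. Presynaptic genes had a median log2 difference of 0.22, and 32 of 34 were higher with the compound. Unc13a, a priming factor of synaptic vesicles, had 13.2 ± 1.23 FPKM with and 9.06 ± 0.156 FPKM without it, and Sncb 56.8 ± 6.09 against 39.8 ± 3.66 FPKM (SD, n = 3). All 18 interneuron markers were higher (median 0.34), with Slc32a1, the vesicular GABA transporter, at 17.1 ± 1.76 against 11.9 ± 1.04 FPKM. Calcium channel subunits had a median of 0.18 (19 of 20 higher), with Cacna2d2 at 14.5 ± 2.84 against 9.57 ± 0.591 FPKM, Cacnb1 at 15.5 ± 1.24 against 11.3 ± 0.599 FPKM and Cacna1b at 13.2 ± 4.53 against 9.21 ± 1.84 FPKM.

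Receptors had a median of 0.19 (27 of 29 higher), with Grin2d at 2.61 ± 0.541 against 1.24 ± 0.254 FPKM. Axonal cytoskeleton genes had a median of 0.15 (26 of 32 higher), with Nefl, the neurofilament light chain, at 25.5 ± 2.30 against 17.8 ± 2.74 FPKM. Sodium and potassium channels had a median of 0.12 (23 of 27 higher). Cell cycle genes had a median of -0.14 (32 of 37 lower), with Ccne2, cyclin E2, at 21.2 ± 1.05 against 29.7 ± 1.93 FPKM and Top2a at 70.2 ± 11.2 against 89.7 ± 9.13 FPKM. Of these 7 lists no member passed, also when adjusted over the list alone. Astroglia markers had a median of -0.09 and progenitor markers -0.11, and neither list was called (adjusted p = 0.402 and 0.325).

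Camera called the 7 lists, 6 up and 1 down, with adjusted p from 1.89e-09 to 0.00364; none passed with an estimated correlation (lowest adjusted p = 0.671 with an estimated correlation) or with fry's directional test (lowest adjusted p = 0.880), and its mixed test called 0. Limma gave 370 genes at an unadjusted p under 0.05 and, with the pairs as a block, 0 called genes and 1108 at an unadjusted p under 0.05. With the block camera called 13 lists, adding the neighbours of Smn1, sensory neuron markers, axon guidance, Hox groups 9 to 13, immediate early and stress response genes, of which none passed with an estimated correlation (lowest adjusted p = 0.299 with an estimated correlation). With the block fry's mixed test called 6 lists, motoneuron markers (adjusted p = 0.00593), axonal cytoskeleton genes (adjusted p = 0.0375), and presynaptic, Hox groups 9 to 13, interferon response and interneuron genes (adjusted p = 0.0287 for each). Leaving out untreated SMA library 2 raised the list count to 11.

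The named genes nearest to the threshold were PVT1_1 at 6.27 ± 0.883 against 1.85 ± 0.403 FPKM, Tmem198, a modulator of Wnt signalling, at 4.31 ± 0.744 against 2.05 ± 0.272 FPKM, Zbtb4 and Fam98c, all higher with the compound (SD, n = 3; limma, adjusted p = 0.999 for each). Zcchc9, at 9.03 ± 0.460 against 13.2 ± 1.51 FPKM, Tmsb15b1 and uc_338 were lower. The genotype difference and this treatment effect were inversely correlated across genes, with r = -0.516. Both use the untreated SMA libraries, which alone gave r = -0.497 in simulated independent libraries without any effect and -0.392 in simulated same-numbered pairs. The covariance was -0.0303, against a simulated -0.0246 for independent libraries and -0.0152 for same-numbered pairs. The shared libraries thus give an inverse relation without any effect, so the correlation is no evidence that the compound reverses the genotype difference. Without treated SMA library 2 the correlation was -0.145, and without untreated control library 1 it was -0.339.

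The interaction asks whether R-Roscovitine acted differently in SMA and control cultures. No gene passed by limma (lowest adjusted p = 0.819, PVT1_1). PVT1_1 was higher with the compound in SMA and lower in control cultures, at 4.95 ± 0.498 FPKM treated and 9.08 ± 4.36 FPKM untreated in the latter (SD, n = 3). Tmem198 and Lrsam1, a ubiquitin ligase, had interaction terms of 0.96 ± 0.24 and 0.76 ± 0.20 (SE), and Luc7l3, a splicing factor, and uc_338, a short feature on chromosome 8, of -0.88 ± 0.25 and -1.65 ± 0.39. Of the lists, the 16 tested neighbours of Smn1 on chromosome 13 were called (median -0.16, 13 lower; adjusted p = 0.0292, and adjusted p = 0.976 with an estimated correlation). Cenph, a centromere protein, had an interaction of -0.62 ± 0.26 and Gtf2h2, a subunit of TFIIH, of -0.33 ± 0.21, and no member passed when adjusted over the list alone.

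Limma gave 301 genes at an unadjusted p under 0.05 for the interaction and, with the pairs as a block, 0 called genes and 729 at an unadjusted p under 0.05. With that block camera called 7 lists, adding as higher calcium channels (adjusted p = 0.0325), axonal cytoskeleton (adjusted p = 0.00833), interneuron (adjusted p = 0.00833), presynaptic (adjusted p = 0.0188), immediate early (adjusted p = 0.0201) and stress response genes (adjusted p = 0.0467). None of the 7 passed with an estimated correlation (lowest adjusted p = 0.800 with an estimated correlation), and fry's directional test called 0 lists with the block (lowest adjusted p = 0.502) and without it (lowest adjusted p = 0.982), as did its mixed test. Leaving out 1 library at a time gave 0 to 9 lists, with 9 without treated control 1, 8 without untreated control 3, 6 without untreated SMA 1, 5 without treated SMA 3, 4 without untreated control 2, 3 each without untreated SMA 2, treated control 2, treated control 3 or treated SMA 1, 2 without treated SMA 2 and 0 without untreated control 1; the gene count was 1 without untreated control 2. Across genes, the effects of the compound in SMA and control cultures had a correlation of -0.046, and 21 of 32 ways of exchanging treated and untreated within pairs gave one as large (exact one-sided permutation p = 0.656). Without untreated control library 1 that correlation was 0.257, without untreated SMA library 1 0.0794, without treated SMA library 3 0.056 and without treated control library 3 0.00488.

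Averaged over both genotypes, R-Roscovitine moved no single gene past the threshold. Camera called 10 lists, 7 up and 3 down (adjusted p from 3.61e-12 to 0.0182), and none passed with an estimated correlation (lowest adjusted p = 0.614 with an estimated correlation) or with fry's directional test (lowest adjusted p = 0.874), and its mixed test called 0. All 34 presynaptic genes were higher with the compound (median log2 difference 0.19), led by Vamp2 (0.41 ± 0.11 SE), Nrxn3 (0.41 ± 0.14) and Stx1a (0.36 ± 0.13). Of 29 receptors 28 were higher (median 0.20), and all 18 interneuron markers (median 0.23). Of 37 cell cycle genes 36 were lower (median -0.09), with Bub1b at -0.24 ± 0.10 and Cenpf at -0.25 ± 0.11. Tac1, which encodes substance P, was 72.2 ± 30.4 and 55.4 ± 6.18 FPKM in treated control and SMA libraries and 44.7 ± 5.96 and 34.7 ± 9.15 FPKM in untreated ones (SD, n = 3). It differed by 0.66 ± 0.18 and, with Ankrd24 (0.42 ± 0.12), Tmsb15b1 (-0.65 ± 0.17), Cyp4f13 (-0.48 ± 0.13) and Vangl1 (-0.33 ± 0.10), was among the genes nearest to the threshold.

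The other called lists had medians of 0.12 for sodium and potassium channels, 0.11 for calcium channels, 0.10 for mitochondrially encoded transcripts, 0.08 for axonal cytoskeleton genes, -0.06 for ribosomal proteins and -0.09 for histones. The ribosomal protein median was 0.0115 without control 1 in both treatments. Limma called 0 genes, with 253 at an unadjusted p under 0.05, and with the pairs as a block 0 genes, with 900 at an unadjusted p under 0.05 and 14 lists (lowest adjusted p = 0.211 with an estimated correlation). With the block fry's mixed test called 7 lists, with adjusted p from 0.0108 to 0.0447: Hox groups 9 to 13, mitochondrially encoded transcripts, motoneuron and interneuron markers, presynaptic genes, Hox groups 4 to 8 and sensory neuron markers.

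Levels of marker genes were compared between cell types. Several genes that define spinal motoneurons were near 0 in every library: Mnx1 was listed at 0 in all 12, Chat reached at most 0.0605 FPKM, Isl2 0.161, Slc5a7 0.249, Lhx3 0.669 and Isl1 0.845 FPKM. Of 21 motoneuron markers in the files, 9 stayed below 1 FPKM in every library. Others were above it in all 12, such as Foxp1 at 19.7 to 29.3 FPKM, Calca at 5.79 to 20.8 FPKM and Ache at 5.74 to 13.5 FPKM. Of 27 interneuron markers 8 stayed below 1 FPKM in every library, and the median of the mean levels was 2.19 FPKM, against 1.87 FPKM for motoneuron markers. The transmitter genes among them were higher, with Gad1 at 52.8 to 147 FPKM, Slc6a5 at 11.8 to 35.6 FPKM and Slc17a6 at 16.6 to 49.0 FPKM. Vim ranged from 1852 to 3278 FPKM, Acta2 from 1428 to 2625 FPKM and Fabp7, a radial glia gene, from 165 to 854 FPKM. Of 11 pericyte and smooth muscle markers, Acta2 among them, 6 stayed below 1 FPKM in every library, with Myh11 at a mean of 0.0887 FPKM and a list median of 0.477 FPKM. Hox genes of groups 4 to 8 had a median of 25.3 FPKM, from Hoxa4 at a mean of 2.19 to Hoxb8 at 167 FPKM. Those of groups 9 to 13 had a median of 2.15 FPKM, with 6 of 16 below 1 FPKM in every library and Hoxb9 highest at a mean of 172 FPKM. Col1a1, a fibroblast gene, had 63.1 FPKM untreated and 63.2 FPKM treated in control libraries numbered 2 and 7.10 to 18.1 FPKM in the other 10 libraries. The highest level in any library was 7.83 FPKM among endothelial genes (Kdr), 5.03 FPKM among macrophage genes (Cd68), 4.80 FPKM among skeletal muscle genes (Myh8) and 0.717 FPKM among erythroid genes (Hba-a1).

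**Figure D3:**
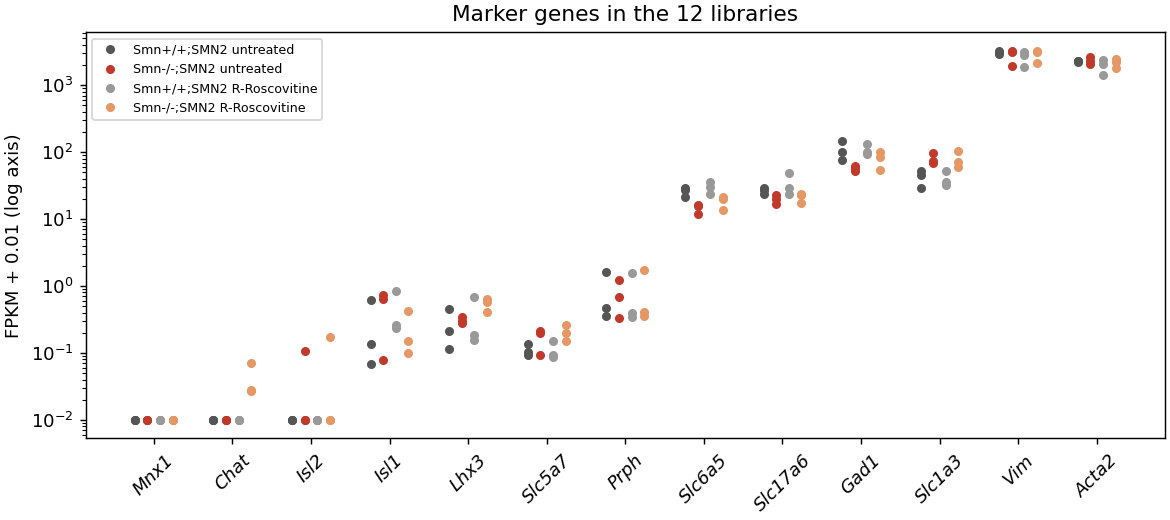
FPKM + 0.01 (log axis) of 13 marker genes in the 12 libraries, coloured by group. Mnx1, Chat, Isl2, Isl1, Lhx3 and Slc5a7 lie below 1 FPKM in every library, and Gad1, Slc6a5 and Slc17a6 above 10 FPKM.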

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

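The result given here was picked by a rule for effects that differ between genotypes, and the split count was planned before the result was seen. The 16 tested neighbours of Smn1 on chromosome 13 had a median log2 interaction of -0.164, so that their difference with R-Roscovitine was lower in SMA than in control cultures, by camera's test of the difference (adjusted p = 0.0292, and adjusted p = 0.976 with an estimated correlation). It was the 1 list called for the interaction, where the highest count in the other splits that keep same-numbered pairs together was 6. No explanation was tested.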

How the results depend on the processing

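Leaving out control library 1 in both treatments, the pair block, the pairs as a random effect and the pair means were chosen after the results were seen. Apart from the values below, named genes kept their direction and side of the threshold in 10272 comparisons with an alternative, lost the call in 469, gained it in 201 and moved in 91, and none reversed; lists kept theirs in 1322, lost the call in 268 and reversed in 7. Of the 675 genes of the averaged genotype effect, 652 were also called with a pseudocount of 0.1, 542 with a filter of 5 FPKM and 567 with TPM rescaling. The pair block changed no other call than those given beside the results. The cause of the changes below was not tested, except where fewer libraries entered a fit. The depth of 19.5 to 28.7 M reads left values between 1 and 2 FPKM with a Cufflinks interval of 25.8% to 33.6% of the value to each side.

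For the averaged genotype effect, 1 gene was called with no filter beyond values above 0, 1980 with library weights, 1746 with the replicate number as a block, 38 without control 1 in both treatments, 3 with pairs as a random effect and 1 with pair means. For the treated genotype effect, TPM rescaling gave 2 genes, weights 12 and the number block 230. For the untreated one, a pseudocount of 0.1 gave 2, TPM rescaling 2, weights 359, the number block 318 and leaving out control 1 in both treatments 2. The interaction had 1 gene with no filter. Same-numbered libraries of different genotypes did not all correlate above 0.1 (treated 0.252, 0.045 and 0.288, untreated -0.054, 0.145 and -0.016), so they were not treated as pairs. All 6 treated libraries and 2 of 6 untreated ones correlated best with their own number, a hint that the number marks something shared across genotypes, as the Xist levels of number 3 also do. The correlation of both genotype effects was 0.577 with a pseudocount of 0.1.

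With an estimated correlation 0 lists were called in each of the 7 comparisons. Fry's directional test called 3 for the averaged genotype effect, 0 with pair means, and 0 in the other 6. Without control 1 in both treatments the list counts were 9 for the averaged and 6 for the treated genotype effect, 7 for the interaction and 2 for treatment in controls. For the interaction, no filter gave 0 lists, a filter of 5 FPKM 3, the number block 5 and the pair block 7; the pair block gave 13 for treatment in SMA. With quantile normalization the mitochondrially encoded median was 0.0127 in the averaged and -0.0266 in the treated genotype effect. Without control 1 in both treatments the ribosomal protein median was 0.0441 for treatment in controls and 0.0115 for the averaged treatment effect.

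Leaving out each library in turn gave 6 to 1350 genes for the averaged, 1 to 211 for the treated and 1 to 6 for the untreated genotype effect, 0 to 1 for the interaction and 0 to 0 for the treatment effects. Lists ranged from 11 to 17, 6 to 12 and 13 to 17 for these genotype effects, 0 to 9 for the interaction, 6 to 11 for treatment in SMA, 1 to 11 for treatment in controls and 8 to 15 for the averaged treatment effect. The log2 difference of Smn1 ranged from -2.58 to -2.34 treated and -2.49 to -2.12 untreated. The correlation of both genotype effects ranged from 0.541 to 0.732, that of both treatment effects from -0.215 to 0.257, and that of genotype and treatment effect in SMA from -0.664 to -0.145. For treatment in controls the cell cycle median ranged from -0.130 to 0.0281 and the presynaptic median from -0.0327 to 0.236; they changed direction without treated control 1 (0.0281 and -0.0327) and without untreated control 3 (0.0118 and -0.00993).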

Other observations

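The tests of cell types and of motoneuron markers below were chosen after the results were seen. Xist, which is transcribed from the inactive X chromosome of female cells, had 207 to 228 FPKM in the libraries numbered 3 of all 4 groups and at most 0.332 FPKM in the other 8. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at most 0.102 FPKM in the libraries numbered 3. Each group thus held 1 library of this kind, so the genotypes and treatments were balanced for it.

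Progenitor and astroglia markers were higher in SMA libraries. A lower share of neurons would raise the markers of every other cell type alike only if those types kept their proportions to each other. Astroglia and progenitor markers differed by 0.69 ± 0.19 and fibroblast, smooth muscle, endothelial and macrophage markers by -0.03 ± 0.17 (log2, SE from the means of 3 treated and untreated pairs per genotype), a gap of 0.728 ± 0.267. The gap was more than 2 SE, but from 3 means against 3. Presynaptic genes differed by -0.31 ± 0.15, the direction that a lower neuron share predicts. Control libraries numbered 2 held the highest Col1a1 levels, so the other cell types may not have kept their proportions. The gap therefore does not decide on a lower neuron share. A lower neuron share, more progenitors and glia in the cultures, or higher expression in each such cell may each account for the higher markers. All stay open, as does a difference between cultures that is unrelated to genotype.

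Of 21 motoneuron markers, 9 were below 1 FPKM in every library, while others such as Foxp1 (19.7 to 29.3 FPKM) and Calca (5.79 to 20.8 FPKM) were above it. Of these 9 members, 6 had a status of OK in every library and a value above 0 in at least 6. This argues against failed Cufflinks estimates for them, though the criterion was chosen after the levels were seen. Mnx1, Isl2 and Chat also had a status of OK throughout. They were above 0 in only 0, 2 and 3 libraries, so they missed the criterion. In 12 of 12 libraries Gad1, Gad2 and Slc32a1 each exceeded Chat, Slc5a7, Isl1, Isl2, Mnx1 and Lhx3. These levels had been seen before and support no explanation: few motoneurons among the cells sequenced and low expression of these genes in cultured motoneurons both stay open.

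The 675 genes of the averaged genotype effect came from a fit that counts both libraries of a same-numbered pair as independent. Among the other splits that keep pairs together the highest count was 97, below the real count but above 0. Pair counting may thus add calls, and how many of the 675 it added stays open. Simulated libraries with changed genes gave 8.6 false calls on average without such pairs and 35.8 with a correlation of 0.38 within pairs. Pair counting thus added calls there. With no changed gene the averages were 0 false calls without and 0.6 with such pairs. The simulated genes are independent, unlike real ones, so these averages do not give the number added among the 675. With the pairs as a random effect 3 genes were called, and with 1 mean per pair 1.

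Other splits of the libraries were counted for each result. The splits were too few for a share under 0.05 in all comparisons but the averaged treatment effect. For genes, 1 of 10 splits called as many as the real one for the untreated genotype effect (real 1, highest other 0), 1 of 10 for the treated one (1 and 0), 1 of 10 for the averaged one (675 and 97), and 10 of 10 for treatment in controls, treatment in SMA and the interaction, where the real and the highest other count were 0. For lists, 1 of 10 splits called as many for the untreated genotype effect (17 and 12), 6 of 10 for the treated (10 and 16), 4 of 10 for the averaged one (16 and 17), 7 of 10 for treatment in controls (6 and 14), 6 of 10 for treatment in SMA (7 and 14) and 9 of 10 for the interaction (1 and 6). Of the 4 splits that part every pair, the real one included, 1 called as many lists for treatment in controls (highest other 3) and 2 for treatment in SMA (highest other 8). For the averaged treatment effect 32 of 32 splits called as many genes (0 and 0) and 3 of 32 as many lists (10 and 11), so chance is not excluded there. Splits that ignore the same-numbered pairs called up to 120 genes for the interaction, against 0 for the real one. They exchange genotypes separately in each treatment, so the genotype difference itself can enter that count, and nothing is concluded from it. Splits of the libraries of 1 genotype called up to 14 lists, against 6 and 7 for the real ones. The latter count points to a structure of the samples.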
